A study of Homo sapiens with 31 samples.

How the data were processed

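The series profiled chromatin of human CD34+ blood stem and progenitor cells, taken from mobilised peripheral blood of donors, by chromatin immunoprecipitation followed by sequencing (ChIP-seq). It holds 31 samples. Of these, 29 are immunoprecipitations of SMAD1, GATA1, GATA2 or H3K27ac and their inputs, taken at day 0, hour 6 and days 3, 4 and 5 of erythroid differentiation after a 2 h pulse of 25 ng/ml BMP4. The other 2 samples are a SMAD2 immunoprecipitation and its input, both at day 0. The processed data used here are 1 peak list, that of the day 0 SMAD2 library; the other 30 samples are not analysed here. The group has 1 library, so nothing below has a replicate check, no test across samples was made and no p-value is attached to a comparison. The labels of the SMAD2 library disagree on its stimulus: both give a 2 h pulse at 10 ng/ml, but the description names BMP4 and the treatment protocol names TGF-beta.

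Reads were aligned to hg19 with Bowtie and peaks were called with MACS2 2.0, per the submitters' processing notes; the version of Bowtie, the filters, the control used and the calling threshold are not given in the sources used here. The deposited fold enrichment of each peak is a ratio of ChIP to control at the summit, the base of highest pile-up, as the authors' peak caller wrote it. The deposited p-value and q-value of each peak are given as −log10 at the same base, also by the authors' peak caller. The deposited score is a whole number close to 10 times the −log10 q, and was not used. The largest q in the list was 0.0495, just under a threshold of 0.05. Peaks were called on 1 library and not on pooled libraries, as far as the labels say. Coordinates are those of hg19, given 1-based.

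The list holds 69898 peaks. Summaries cover the 67811 peaks on the 22 autosomes. The 2087 peaks on other sequences stay out of them, because the cells came from donors, and only the mitochondrial peaks among them are described, in the closing section. A control with SMAD2 binding lost was not analysed here, so the background of each peak is the control expectation that the peak caller itself used.

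The list gives no read numbers, but fold and p together fix them. MACS2 writes the fold as the ChIP pile-up plus 1 over the control expectation plus 1, and the p as a Poisson upper tail. No source states these formulas for this list; they were inferred from its values. For every peak the whole number of ChIP fragments that best gives both listed values was taken. In 100% of the peaks the recomputed −log10 p lay within 0.001 of the listed one, with a largest difference of 0.000262. At 2 peaks another whole number also lay within 0.001. On 65407 simulated peaks the procedure recovered 100% of the pile-ups. The control expectation follows from the fold. Its lowest value, 0.995 fragments, is the genome background. The shortest peak was 149 bp, which was taken as the fragment length. The highest control expectation, divided by 298 (2 strands of 149 start positions each, if each position and strand is counted once), gives a scale of 0.619 from control to ChIP fragments. With this scale 68.7% of autosomal peaks had a control expectation equal to a whole number of control fragments (within 0.0002 after scaling), 19.5% a whole number of reads in a 1 kb window and 6.49% in a 10 kb window, 5.25% stood at the genome background and 0.0723% met none of these. With a fragment 1 base shorter or longer the first share was 0.00147% or 0.814%. The ChIP library was thus smaller than the control by the factor 0.619. If the effective genome size was 2.7e+09 bases, an assumption, 18.0 M ChIP reads and 29.1 M control reads were kept. Fragment numbers below are these recovered values. Counts are compressed as they approach 298, so no interval is given for the fragment numbers of named peaks; densities have exact 95% Poisson intervals. All intervals cover counting error only. They treat peaks as independent, whereas peaks lay in groups along the chromosomes, so the intervals are likely too narrow. PCR reads without molecular identifiers are also not independent molecules.

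Peaks per Mb were computed over the span from the first to the last summit of each chromosome. The share of summits with another summit within 10 kb was set against 100 seeded draws of as many uniform positions per autosome; the draws ignore mappability. On 67811 simulated uniform summits the share was 39.5%, against a mean of 39.6% in their draws; with 10.0% of the summits planted beside others it was 49.4%, against 39.6%. Peaks were also cut into 5 groups of equal size (quintiles) by −log10 q. Medians have binomial order-statistic intervals and shares have Wilson intervals, both at 95%. Peaks named in the text are the 10 autosomal peaks with the highest −log10 q and the peak with the highest fold, a rule set in advance; groups of linked summits, the chromosomes set against each other and the recovery of fragments were chosen after values were seen. Other settings fixed before the data were examined were a −log10 q of at least 5 or 10, a fold of at least 5, the top 10000 peaks, regions closer than 200 bp counted once, neighbour distances of 5 and 20 kb and ranking by fold. Settings added after seeing the data were limits on the control expectation, a fold without the pseudocount of 1, draws within 1 Mb windows and ranking by fragments.

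Analyses of peak location relative to genes, of gene lists and of sequence motifs were intended but not run, because no genome or annotation of hg19 was used here; peaks are therefore named by position and not by gene. Analyses were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.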

Results

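SMAD2 is a transcription factor that receptors of the TGF-beta and activin type phosphorylate, whereas receptors of the BMP type act through SMAD1 and its relatives. Its binding was mapped by ChIP-seq in human CD34+ haematopoietic stem and progenitor cells at day 0, before erythroid differentiation, after a 2 h pulse of 10 ng/ml ligand. The labels name the ligand as BMP4 in the description and as TGF-beta in the treatment protocol, so the stimulus behind the peaks remains open. The data are the peak list of 1 library. It shows where SMAD2 peaks were called over control in these cells, how strongly, and how they were arranged along the genome. These peaks are called sites below, although no control with SMAD2 binding lost was analysed. The list allows no comparison with SMAD1, the GATA factors, H3K27ac or later time points, which were not analysed here.

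SMAD2 enrichment was found at 67811 autosomal sites, most of them narrow and of moderate strength. The median site was 232 bp wide (95% interval of the median 231 to 232 bp) and its summit was enriched 5.81-fold (5.81 to 5.85) over control. The summit of the median site carried 31 ChIP fragments, with 13 at the 10th and 85 at the 90th percentile of sites. A fold of at least 10 was reached at 11799 sites, or 17.4% (Wilson interval 17.1 to 17.7%), a fold of at least 20 at 1520 sites, and a fold of at least 40 at 73 sites. At the weak end 217 sites had a fold under 2. Together the sites covered 17.9 Mb. The widest was 3817 bp and the narrowest 149 bp, which is also the fragment length. The evidence per site ranged widely: the median −log10 q was 12.3, with 4.63 at the 10th and 55.6 at the 90th percentile, and 2389 sites had a −log10 q of at least 100. A stricter −log10 q of at least 10 left 39590 sites.

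The strongest SMAD2 sites lay on 8 autosomes, with listed folds of 27.04 to 52.2 over control. The site with the highest −log10 q, 377, was a 503 bp region on chromosome 10 (hg19, 86284730 to 86285232). Its summit held 286 ChIP fragments where 4.95 were expected from the control, a listed fold of 48.2. On chromosome 2 a 626 bp site (218012312 to 218012937) held 263 fragments, 33.8-fold over control, and a 377 bp site (222308801 to 222309177) held 223 fragments, 47.5-fold. On chromosome 6 a site from 4928656 to 4929078 held 213 fragments and had the highest listed fold of the 10, 52.2. Chromosome 16 (50874850 to 50875683) and chromosome 3 (128335370 to 128335837) carried sites with 282 and 278 fragments. Their listed folds were 27.5 and 27.04, with 9.29 and 9.32 fragments expected there. The counts at the 10 sites stood at 71.5% to 96.0% of the most that can be counted, so the ceiling lowers all 10 folds. Their controls were about 5 to 15 fragments before scaling. Picking sites by −log10 q tends to favour low draws of the control, which raises the fold. The net error of these folds and their order are therefore not settled. A second site on chromosome 10, 845 bp wide (11183298 to 11184142), held 245 fragments at 37.4-fold. The remaining sites of the 10 lay on chromosome 7 (12685689 to 12686228), chromosome 17 (37082927 to 37083371) and chromosome 8 (59754617 to 59755019), with 217, 215 and 215 fragments and folds of 46.2, 45.8 and 45.8. These last 3 fragment numbers differ by at most 2, so the sites cannot be ranked. Of the 10 sites, 9 had another summit within 10 kb, as did 77.4% of the strongest quintile by −log10 q. The highest listed fold, 71.7, belonged to a 378 bp site on chromosome 3 (114623479 to 114623856), with 154 fragments where 1.16 were expected. The count stood at 51.7% of the ceiling, which lowers this fold. Choosing the highest fold of the list over a control near the background tends to raise it. Its net error is therefore not settled, nor is its rank above the 10 sites, which stood closer to the ceiling. A further summit lay 546 bp from this chromosome 3 site.

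**Figure D1:**
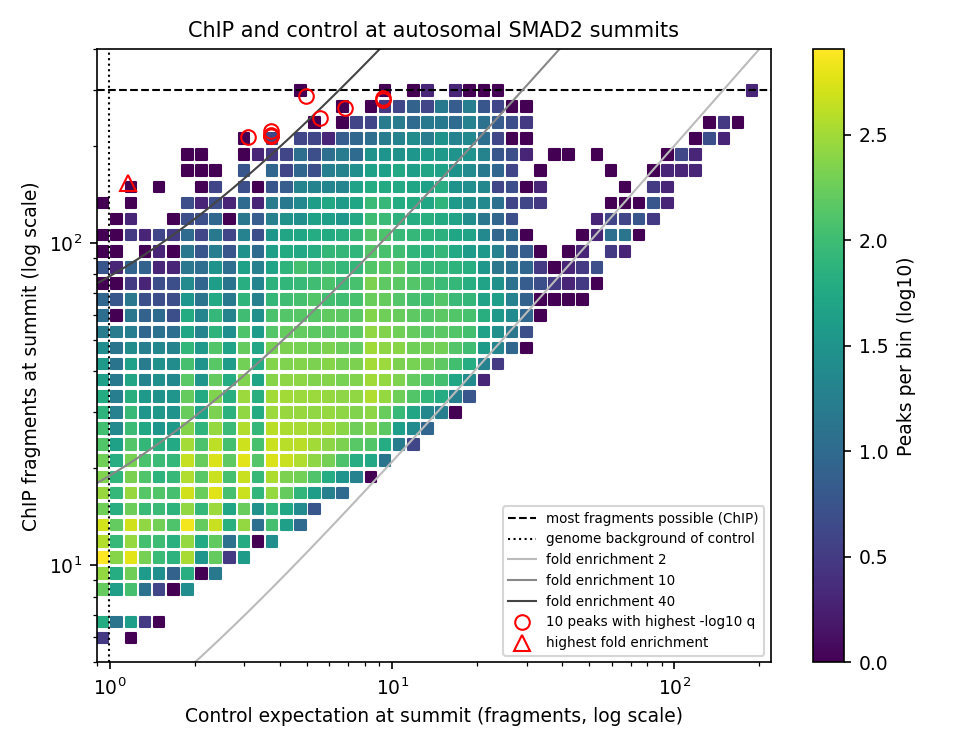
ChIP fragments at the summit (vertical, log scale) against the control expectation in fragments (horizontal, log scale) for 67811 autosomal peaks, binned and coloured by the log10 number of peaks per bin. Red circles mark the 10 peaks with the highest −log10 q and the triangle the highest fold, 71.7; the dashed line is the most fragments that can be counted, 298. The 30 peaks with a control of 149 fragments or more before scaling lie below the line of a 2-fold enrichment, at 1.32 to 1.87.

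Fragment numbers approached a ceiling at some sites, both strong and weak. With each start position and strand counted once, at most 298 fragments can cover a base, and the highest number in the list was 296. At 36 autosomal sites the summit held 90% of that number or more. The site with the most ChIP fragments lay on chromosome 11 (113953377 to 113953986). It held 296 fragments where 23.5 were expected from the control, a listed fold of 12.1. The ceiling lowers this fold, but its control is also a count with error, so the net error is not settled. Of the 5 sites with the most fragments, 2 were weak sites over very high control, on chromosome 1 (121484407 to 121485435) and chromosome 7 (61968696 to 61969638). They held 290 and 288 fragments where 184.5 and 179.6 were expected, with listed folds of 1.57 and 1.60. Before scaling, the control at both sites also stood at 95% of the ceiling or more. The ceiling thus bears on both sides of these folds, and its net effect on them is not known. These sites were named after their values were seen.

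Control DNA was itself raised at most SMAD2 sites. The median expectation at a summit was 4.36 times the genome background, equal to 7 control fragments before scaling. Only 5.25% of sites (Wilson interval 5.09 to 5.42%) stood at the genome background, whereas 41.9% (41.6 to 42.3%) had a control of at least 5 times and 1088 sites at least 20 times the background. The expectation is the largest of several control windows and the genome background, so it is an upper value of the local control. The listed fold includes a pseudocount of 1; without it the median was 7.54.

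SMAD2 sites were densest on chromosomes 19, 17 and 22, which are rich in genes, and sparsest on chromosomes 4, 18 and 13, which are poor in genes. No annotation was used here, so a relation of site density to gene content was not tested. Chromosome 19 had 41.3 peaks per Mb (exact Poisson interval 39.7 to 43.0), chromosome 17 had 40.7 (39.3 to 42.1) and chromosome 22 had 40.03 (38.0 to 42.2). Chromosome 4 had 15.4 (14.9 to 16.0), chromosome 18 had 17.5 (16.6 to 18.5) and chromosome 13 had 17.8 (16.9 to 18.6). All autosomes together had 24.3. The density on chromosome 19 was 2.68 times that on chromosome 4, and the intervals of these extremes are far apart. The median control at the summits was also higher on chromosome 19, 7.47 times the genome background, than on chromosome 4, where it was 3.11 times. The median fold ran the other way, at 5.09 on chromosome 19 and 6.29 on chromosome 4.

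The order of the chromosomes differed in sites of low control, a selection that itself keeps few sites of chromosome 19, 121 of 2440, and more of chromosome 4, 1076 of 2943. Among the 15589 sites with a control under 2 times the background, chromosome 19 was the sparsest autosome, with 2.05 peaks per Mb (1.70 to 2.45), and chromosome 3 the densest, with 6.77 (6.41 to 7.14). Chromosome 4 then had 5.63 (5.30 to 5.98), or 2.75 times the density of chromosome 19. Intervals of densities cover counting error in 1 library.

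**Figure D2:**
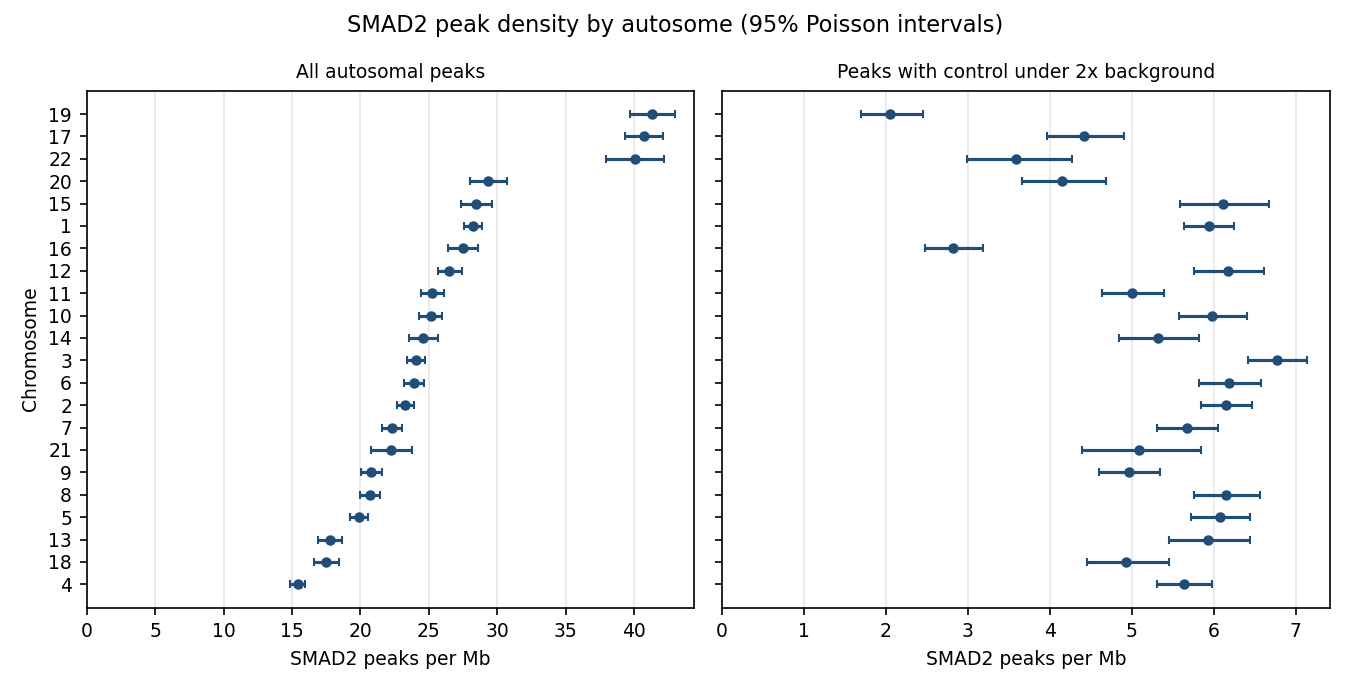
SMAD2 peaks per Mb (horizontal) on each autosome (vertical, ordered by the density of all peaks), for all autosomal peaks on the left and for peaks with a control under 2 times the genome background on the right; points are densities and bars 95% Poisson intervals. Chromosome 19 lies highest on the left, at 41.3, and lowest on the right, at 2.05.

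SMAD2 sites lay in groups along the chromosomes. The median distance from a summit to the nearest other summit was 4854 bp (4785 to 4934 bp), and 67.2% of summits (Wilson interval 66.9 to 67.6%) had another within 10 kb. In uniform draws of as many positions per autosome the mean was 39.6%, and the highest of 100 draws gave 40.2%. Draws that kept the number of peaks in each 1 Mb window gave 51.9% on average and at most 52.3%. Within 5 kb the observed share was 50.7%, against 22.4% in uniform draws and 31.9% in draws within windows. Linking summits closer than 10 kb gave 277 groups of 10 or more summits, which held 5.13% of all summits; the draws within windows gave at most 28 such groups, and their largest group had 26 summits. The largest group, of 30 summits, lay on chromosome 2 (92291079 to 92325529), but its median fold was 1.67 and its median control 65.7 times the background. The next was on chromosome 5 (139015474 to 139091669), with 29 summits, a median fold of 5.07 and a control of 8.09 times the background. It was followed by 26 summits over 90.5 kb of chromosome 3 (30644649 to 30735187), with a median fold of 6.37, a highest fold of 15.9 and a control of 3.20 times the background. A group of 24 summits on chromosome 9 (139539057 to 139595999) had a median fold of 5.32 and a control of 7.16 times the background. The groups of 26 and 24 summits are thus no larger than the largest in the draws. These groups were named after their values were seen.

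**Figure D3:**
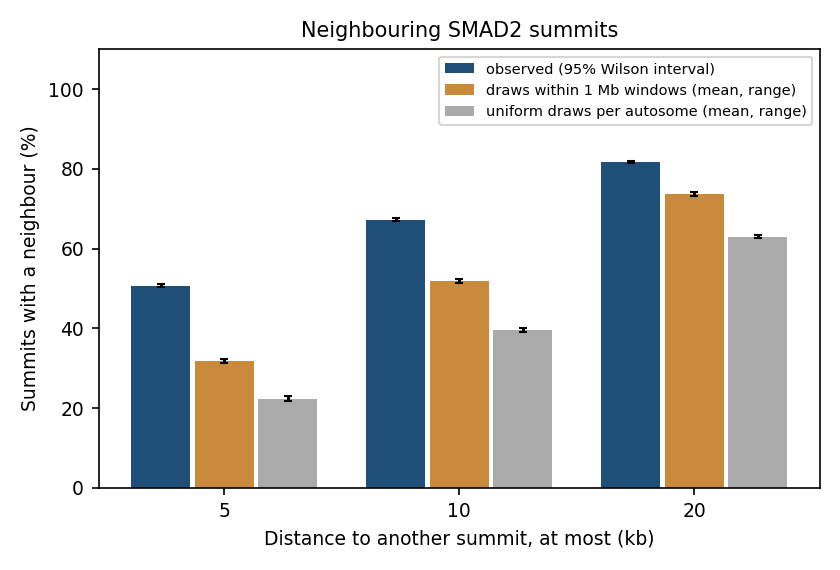
Share of autosomal SMAD2 summits with another summit within 5, 10 or 20 kb (vertical, percent), as observed with 95% Wilson intervals and in 100 random draws (mean, with the lowest and highest draw as bars). At 10 kb the observed 67.2% lies above draws within 1 Mb windows (51.9%) and uniform draws (39.6%).

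Sites with stronger evidence were wider and had more neighbours. The −log10 q is computed from the same fragments and control as the fold, so fragments and fold rise with it largely by construction. Width is read from the same pile-up, so it is not independent of this ranking either. From the weakest to the strongest quintile by −log10 q the median width rose from 172 bp (171 to 173 bp) to 357 bp (355 to 360 bp), and the median number of fragments from 16 to 83. The share with another summit within 10 kb was 62.2% (61.4 to 63.0%) in the weakest and 77.4% (76.7 to 78.1%) in the strongest quintile. The median fold rose from 3.75 to 12.0, and the median control was 3.74 times the background in the weakest and 6.23 times in the strongest quintile. Ranked by fold, the share was as high at both ends and lower between them. It was 70.2% (69.4 to 70.9%) in the weakest quintile, then 66.8%, 63.5% (62.7 to 64.4%) and 65.5%, and 70.1% (69.3 to 70.8%) in the strongest. The median control was highest, 8.72 times the background, in the quintile of lowest fold. Ranked by ChIP fragments, the share was 52.2% in the lowest and 79.6% in the highest quintile. Peaks of 1 list are not replicates, so these are descriptions of this library.

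**Figure D4:**
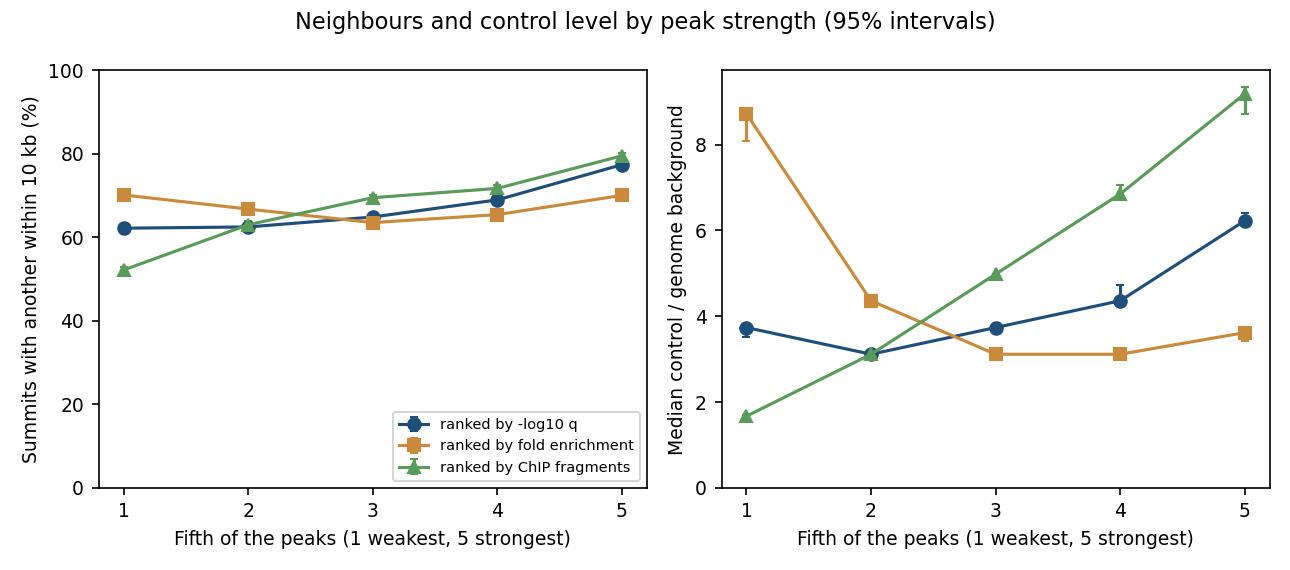
Share of summits with another within 10 kb (left, percent) and median control over the genome background (right) for 5 equal groups of autosomal peaks from weakest (1) to strongest (5), ranked by −log10 q, fold or ChIP fragments; bars are 95% intervals. By −log10 q the share goes from 62.2% to 77.4%, whereas by fold it is 70.2% and 70.1% at the ends and 63.5% in the middle.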

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

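All tests in this part were chosen after the fragment numbers had been seen. The list contains 14 peaks on the mitochondrial sequence, outside the nuclear genome that the report describes, and these passed the peak caller's threshold over its control. Their folds lay between 1.40 and 1.70, with −log10 q from 4.46 to 14.0. The summits held 258 to 296 ChIP fragments and the control held 281 to 298 before scaling, so both were near the most that can be counted, 298. At 13 of the 14 peaks the control lay at 95% of that limit or more. A candidate explanation is that counting each start position once capped both libraries alike, after which the control was multiplied by 0.619. This explanation was drawn from the same values, so they are no independent test of it and it stays open. No biological explanation was tested.

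On the autosomes, 30 peaks had a control of 149 fragments or more, with a median fold of 1.58 and a median ratio of ChIP to control fragments before scaling of 0.981. For the 29 of them below the limit, correcting both pile-ups for it gave a median ratio of ChIP to scaled control of 1.56, against 1.59 before, and the 10th percentile of the ratio before scaling was 0.901; this does not decide whether the limit made these peaks. In sequence where few positions can be mapped the limit is lower, and mappability was not analysed here. For the 1058 autosomal peaks with a control from 20 times the background up to 149 fragments, ChIP fragments exceeded control fragments before scaling, with a median ratio of 1.84 and a 10th percentile of 1.19. A limit shared by both libraries moves this ratio towards 1 and not past it, so a ratio as high as the median is not what such a limit alone gives. The 10th percentile decides nothing, because the calling threshold kept low ratios out. No peak of this set held fewer than 39 ChIP fragments, and its lowest control was 32.5 fragments. For peaks with a ratio near 1 the origin stays open.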

How the results depend on the processing

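No paired analysis was possible because the SMAD2 group has 1 sample, and no replicate could be left out. The intended settings for peak location, gene lists and motifs were not run. Limits on the control, draws within 1 Mb windows, the fold without pseudocount and the ranking by fragments were added after seeing the data. Stricter thresholds keep fewer peaks by construction, which lowers the share with neighbours; for other changes below the cause was not tested. Of 67811 autosomal peaks, 39590 had a −log10 q of at least 10, 42610 a fold of at least 5 and 15589 a control under 2 times the background, and 10000 were kept by rank. The share with a neighbour within 10 kb, 67.2%, became 64.6% and 56.7% at a −log10 q of at least 5 and 10, 54.6% at a fold of at least 5 and 33.95% for the top 10000. It was 65.6% with close regions counted once, 66.8% without controls of at least 20 times the background and 26.3% with only controls under 2 times the background. Within 5 and 20 kb it was 50.7% and 81.7%. Its excess over uniform draws, 27.6 points, was positive in all 10 other settings: 28.8, 30.9 and 26.4 points at a −log10 q of at least 5, of at least 10 and for the top 10000, 26.9 with close regions counted once, 15.4 with low control only, 28.3 and 18.6 within 5 and 20 kb, and 15.3 against draws within 1 Mb windows. The excess in neighbours of the strongest over the weakest quintile, 15.2 points, became 17.9 and 17.7 at a −log10 q of at least 5 and 10, 25.6 at a fold of at least 5 and 14.1 for the top 10000. It was 16.7 with close regions counted once, 7.42 with low control only and 27.4 when ranked by fragments. Ranked by fold it was −0.0981 points, within counting error of 0, with a lower share in the quintiles between. The log2 ratio of peak density of chromosome 19 over 4, 1.42, was −1.46 with low control only. That selection kept 121 of 2440 peaks on chromosome 19 and 1076 of 2943 on chromosome 4. The median control was 7.47 times the background on chromosome 19 and 3.11 times on chromosome 4, so the selection removed more of the former. In the other 6 settings the log2 ratio was positive, from 0.99 to 1.95. The excess in median width of the strongest over the weakest quintile, 185 bp, ranged from 115 bp with low control only to 211 bp at a fold of at least 5. Ranked by fold it was 131 bp. The median width, 232 bp, ranged from 197 bp with low control only to 377 bp for the top 10000. The median fold, 5.81, was higher in every other setting, up to 12.9 for the top 10000. Depth limits the weak end of the list, where the fewest fragments at a summit were 6, and the ceiling of 298 limits the strong end.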

Other observations

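The strongest quintile of sites by −log10 q held sites of both arrangements, alone and in groups, a split chosen after seeing the data. In it, 3060 sites had no other summit within 10 kb. They had a median fold of 12.9 (95% interval 12.7 to 13.1), a median width of 337 bp (334 to 342 bp) and 71 ChIP fragments (70 to 73), over a control of 4.68 times the background (4.36 to 4.98). The other 10502 sites had a neighbour. Their fold was lower, 11.7 (11.6 to 11.8), their width greater, 363 bp (360 to 365 bp), and their summits held 87 fragments (86 to 88) over a control of 6.85 times the background. These differences exceed the intervals of the medians, within 1 library, but the intervals treat sites as independent. The quintile was also cut by −log10 q, which is computed from fragments and control. At a given −log10 q a higher control goes with more fragments and a lower fold. The differences in fold and fragments are therefore no separate trait of sites with neighbours.

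The tests that follow were all chosen after the observed share of neighbours and the control values had been seen; for the merged summits and the sites of low control, bounds were set before their shares were computed. Summits lay closer together than uniform placement gives. The share with a neighbour within 10 kb, 67.2%, was above the highest of 100 draws that kept the number of peaks in each 1 Mb window, 52.3%, which argues against regional differences at that scale as the whole cause. Counting summits closer than 1 kb once left 61.1%, against at most 48.6% in draws. This argues against single sites called several times within 1 kb as the whole cause. A part of the share may still come from such calls, and single sites with summits further apart stay open. Among the sites with a control under 2 times the background the share was 26.3%, against at most 16.2%, which argues against raised control as the whole cause. Uneven mappability or chromatin openness at smaller scales stays open, and no biological explanation was tested.

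The control was raised at SMAD2 summits, with a median expectation of 4.33 fragments against a genome background of 0.995. Taking the largest of the control windows over evenly spread reads gave a median of 1.24 in simulation; the observed median was 3.50 times that, so this choice over even reads is not enough. Carry-over of ChIP fragments into the control was judged at a rate of 5.20%. This rate is the 5th percentile of control over ChIP fragments at 443 peaks with at least 200 fragments. At that rate carry-over could supply 18.9% of the excess in the weakest quintile. Under 10% would have counted against it and at least 50% for it. The rate may be too high: the chromosome 6 site named above had about 5 control fragments for 213, a lower ratio. A rate shared by all sites could exceed that ratio only by counting error. The share of 18.9% lies between the 2 bounds, so the test does not decide, and a contribution of carry-over stays open. Uneven control coverage, such as input DNA that shears more readily in open chromatin, may be another source and was not tested.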
